A study of Mus musculus with 2 samples.

How the data were processed

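Cells from testes of mice at postnatal day 20 were profiled by droplet single-cell RNA sequencing, with 1 wild-type (WT) library and 1 library labelled as Dis3 knockout (KO). Per the labels, the ablation was in spermatocytes; the means of deletion and the number of animals behind each library are not given in the sources used here. Per the labels' protocols, testes were dissociated with trypsin and EDTA, libraries were made with the 10x Genomics Chromium 3' version 3 chemistry, and sequencing was done on a NovaSeq instrument. Per the submitters' processing notes, bcl2fastq and Cell Ranger 3.1 were used with the mm10 genome build. The annotation release, the settings for calling cells and the handling of doublets are not given in the sources used here.

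The deposited files used here were a list of cell barcodes and a list of gene features for each library. The barcode lists hold 1 barcode of 16 bases per line, left by the authors after the filtering that the file names record. The feature lists hold an Ensembl identifier, a symbol and a feature type per line. Neither kind of file holds a measured value per gene or per cell. Transcript counts per cell were not used here. Comparisons that need them were planned before the data were examined and were not analysed here. They comprise the Dis3 level per cell class, the share of cells per class and per spermatocyte substage, the expression difference between genotypes within a class, and the share of sex chromosome transcripts in spermatocytes. The depth of each library in transcripts is therefore unknown. The genotype labels could not be checked against the level of the targeted gene.

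Samples were grouped by the genotype label. Because each genotype had 1 library, no test between genotypes was made, and no value carries a replicate error. Barcode numbers are given with exact Poisson 95% intervals and shares with exact Clopper-Pearson 95% intervals. These intervals cover counting error only, and do not cover differences in cell loading, dissociation or the calling of cells.

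Barcodes present in both lists were counted by exact match. Their number was compared with independent draws from a kit list of 6794880 barcodes, a size taken from general knowledge of the kit. An exact one-sided binomial test and 10000 simulated pairs of draws were used. Both took every listed barcode as equally frequent. The test compares these libraries, not the genotypes. It was tested on simulated data with 6000 barcodes per list. These were drawn from a smaller simulated list of simulated barcodes that gives about 90.0 shared by chance. There, 300 planted shared barcodes were recovered as an excess of 299.07 over chance, and lists with none planted gave an excess of 6.0. The simulated barcodes were equally frequent, as the test assumes, so this check does not cover unequal use of barcodes. The alternatives tried were the reverse complement of one list, 1 mismatch allowed, a barcode count without those in the other list, and a match of features by symbol. A kit list 0.5 times that size and the list size of the earlier kit were added after seeing the data. Uneven barcode composition was measured from the frequencies of blocks of 4 bases in both lists. The reference was even use of all possible sequences, not the composition of the kit's list. The number of each base per shared barcode was compared with 10000 random subsets of each whole list of the same size, two-sided, with Benjamini-Hochberg adjustment over the 4 bases.

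Gene features were matched by identifier to GENCODE release M21, an annotation of GRCm38, which is the same assembly as mm10. All coordinates are 1-based and come from that release. It lacks 50 of the listed identifiers, so the authors' gene list was not made from that release alone. The genes named were fixed before the data were examined: Dis3 and the RNA exosome genes, and 11 lists of marker genes for testicular cell types. The rule would also have named the genes with the largest differences in spermatocytes, which needs expression values. For each named gene, other listed genes with annotated exons that overlap its own exons were counted per strand. On the same strand, reads from overlapping exons can be assigned to either gene or discarded. Whether an opposite-strand overlap affects a count was not examined. Similar sequence at other positions, and how common overlaps are among all listed genes, were not examined either. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.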

Results

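The series examined testes of mice at postnatal day 20, an age at which the first wave of spermatogenesis has brought germ cells into meiosis. It compared 1 WT library with 1 KO library, to describe the cell populations of the testis and the spermatocytes of mice labelled as Dis3 knockouts. The labels place the ablation in spermatocytes. DIS3 is a ribonuclease that works with the RNA exosome, the complex that processes and degrades many kinds of RNA. The values reported here describe the barcodes called as cells and the list of genes used for counting. Expression levels and cell types were not analysed here.

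Similar numbers of cell barcodes were recovered from both genotypes. The WT library had 13918 barcodes (exact Poisson 95% interval 13688 to 14151), and the KO library had 14640 (14404 to 14879). The KO library thus held 722 more barcodes, a ratio of 1.05 (exact 95% interval 1.03 to 1.08 for counting error alone). With 1 library per genotype there was no replicate check, and this difference could not be separated from differences in cell loading or in cell calling. The number of barcodes is the number of droplets called as cells and does not measure the cellularity of the testis.

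The targeted gene, Dis3 (ENSMUSG00000033166), was on the gene list of both libraries. In GRCm38 it occupies chromosome 14 from 99075206 to 99099770 on the minus strand. Its principal transcript in GENCODE M21 has 21 exons and 5150 bases, of which 2176 bases form the 3' untranslated region. The last exon, from 99075206 to 99077465, is 2260 bases long and holds the end of the coding sequence and the whole 3' untranslated region. A 3' library reads mainly this part of a transcript. The exons removed in the knockout are not given in the sources used here, so it is open whether a 3' read would report the deletion. Since the labels place the ablation in spermatocytes, reads from other cells need not report the deletion. No listed gene had exons overlapping those of Dis3 on its own strand. On the opposite strand, Pibf1 (ENSMUSG00000022064, 99099424 to 99254493) overlapped the 5' end of Dis3. Bora (ENSMUSG00000022070), a mitotic regulator of Aurora A and Polo-like kinase 1, ended at 99074540 on the plus strand, beyond the 3' end of Dis3 and without overlap.

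**Figure D1:**
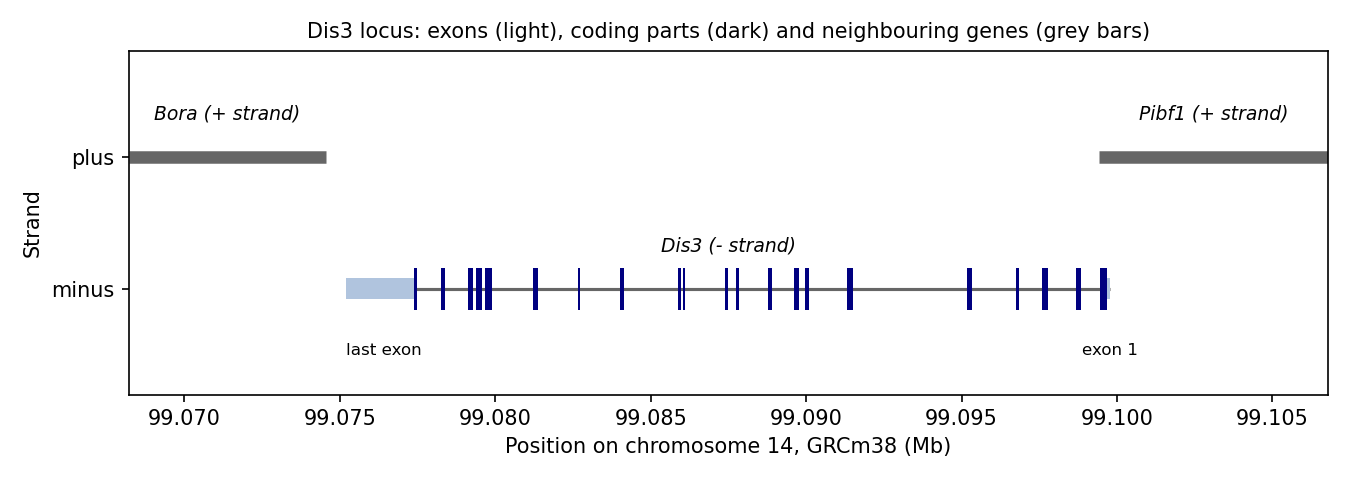
Map of the Dis3 locus on chromosome 14 (GRCm38, position in Mb on the x axis, strand on the y axis), with exons of the principal transcript in light blue, their coding parts in dark blue and neighbouring genes as grey bars. The last of the 21 exons is the longest, is mostly untranslated and lies apart from Bora, while the first exon overlaps Pibf1 on the other strand.

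All 16 genes of the DIS3 and exosome list were on the gene list. They comprise Dis3, its relatives Dis3l and Dis3l2, Exosc1 to Exosc10 (the exosome subunits, of which Exosc10 is a second nuclease), the cofactors Mphosph6 and C1d, and the RNA helicase gene Mtrex. None of them lies on the X chromosome, which is silenced in pachytene spermatocytes. Exosc6 (chromosome 8, 111056339 to 111057664) was the exception in shared sequence, with exons that overlapped Aars, an alanyl-tRNA synthetase gene, on the same strand. A count for Exosc6 may therefore be uncertain. The length of this overlap and its place in the transcript were not examined. Dis3, Exosc2, Exosc3, Exosc4, Exosc5, Exosc8, Exosc9 and Mtrex, 8 of the 16, overlapped exons of a listed gene on the opposite strand only.

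All 56 genes of the 11 marker lists were also on the gene list. Being on this list does not show that a gene or a cell type was detected. The germ cell lists ran from spermatogonia to round spermatids. The spermatogonial list held 6 genes, among them Zbtb16 (a stem and progenitor cell transcription factor) and Stra8 (which promotes meiotic entry). The leptotene and zygotene list held 6, among them Sycp3 and Sycp1 (synaptonemal complex proteins), Dmc1 (a meiotic recombinase) and Prdm9 (which directs recombination hotspots). The pachytene and diplotene list held 6, among them Piwil1 (a PIWI protein of the piRNA pathway), Ldhc (a germ cell lactate dehydrogenase) and Mybl1 (a regulator of the pachytene programme). The round spermatid list held 6, among them Acrv1 and Acr, which encode acrosomal proteins. None of these 24 germ cell markers had exons that overlapped those of another listed gene on the same strand. Gfra1, Uchl1, Sycp3, Ccna1, Spag6 and Tssk1 had such an overlap on the opposite strand.

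The somatic lists held 32 markers. Among the 6 Sertoli genes, Rhox5 (a homeobox gene) is X-linked, whereas Sox9, Amh, Clu, Aard and Wt1 are autosomal. Among the 6 Leydig genes, Cyp11a1 (the cholesterol side-chain cleavage enzyme) shared exonic sequence on the same strand with Gm17322, and Insl3 (a Leydig cell hormone) with Jak3. Counts of both may be uncertain, though the extent of these overlaps was not examined. The steroidogenic genes Cyp17a1, Hsd3b1 and Star had no such overlap. The peritubular myoid (5 genes), endothelial (4), macrophage (5), blood (3) and stromal (3) lists had no same-strand overlap. On the opposite strand, 6 of the 32 somatic markers overlapped exons of a listed gene: Fabp3, Tagln, Des, Csf1r, Alas2 and Pdgfra. The blood marker Alas2 was the other X-linked gene among the markers.

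Both libraries were counted against the same gene list. Its 32285 entries agreed in identifier, symbol and order, with 32245 distinct symbols. In GENCODE M21, 32235 identifiers (99.8%) were found, and 733 of these had another symbol there. The matched genes comprised 21702 protein-coding genes, 9830 long noncoding RNA genes, 697 immunoglobulin and T cell receptor segments and 6 others. By location, 30336 were autosomal, 1084 were on the X chromosome, 725 on the Y chromosome, 13 in the mitochondrial genome and 77 on unplaced scaffolds. A gene could therefore not differ between genotypes through its absence from one list.

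Barcodes present in both libraries were more numerous than independent draws of equally frequent barcodes gave. The lists shared 1867 barcodes, which was 13.4% of the WT list (exact 95% interval 12.9% to 13.99%) and 12.8% of the KO list (12.2% to 13.3%). Independent draws from the kit's barcode list, with every barcode equally frequent, would share 30.0 on average. The observed number was 62.3 times as high (exact one-sided binomial test, log10 p = -2606). Unequal use of the listed barcodes would raise the number that independent draws share. The test cannot separate such use from a link between the libraries. The highest count in 10000 simulated pairs of draws was 53. The size of the kit's list was taken from general knowledge: with a list 0.5 times that size the observed number was 31.1 times as high as independent draws gave, and with the list size of the earlier kit 6.76 times. Outside the shared barcodes, 12051 barcodes were found in the WT list only and 12773 in the KO list only.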

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

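The binomial comparison with independent draws was set before the data were examined; its simulated form and the tests on the bases of the barcodes were chosen after the overlap was seen. The libraries shared 1867 barcodes, against a highest count of 53 in the simulated independent draws of equally frequent barcodes. The overlap lies in the cell identifiers, outside any comparison of expression. Uneven use of 4-base blocks was measured against even use of all possible sequences, not against the kit's list, whose own composition was not available. On that scale, the block frequencies of the whole lists, shared barcodes included, gave a match 1.73 times as often (1.71 times without the shared barcodes). The value falls short of the excess of 62.3 times. It also falls short of the 6.76 times with the list size of the earlier kit, but is no longer less than 0.1 of it. It does not separate the list's own composition from uneven use of the list, so it cannot decide whether uneven use raised the overlap. Sharing that took barcodes without regard to their sequence is argued against as the whole cause. Shared barcodes held 3.63 G bases on average, against 3.93 in WT-only and 3.86 in KO-only barcodes. The shared mean was below every one of 10000 random subsets of either list (lowest 3.77 for WT and 3.70 for KO). The permutation test gave an adjusted p = 0.0002 in both, from the smallest p the subsets can give. Both lists contain the same shared barcodes, so these results are not independent. Molecules of one library counted in the other, for the 13.4% of WT barcodes concerned, stay open as part of the overlap, or as all of it only if the barcodes so carried over differed in sequence from the rest, for example through the number of molecules per droplet; this needs transcript counts per barcode, and whether some whole barcodes are far more frequent among the beads than others was not tested. No biological explanation was tested, because barcodes are assigned by the kit and not by genotype.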

How the results depend on the processing

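The number of shared barcodes stayed above the highest simulated count with each kit list size tried. The other settings run here were no test of direction, as described for each. The reverse complement of one list shared 0 barcodes with the other; reversed barcodes are not draws from the kit's list, so this follows from how the setting is built and is no deficit against the 30.0 of independent draws. Allowing 1 mismatch gave 1869 shared barcodes, 2 more than exact matching, and could not have given fewer, since exact matches are included. Leaving out shared barcodes gave 12051 for WT and 12773 for KO. It removed the same barcodes from both lists, so the difference between them could not change. Matching features by symbol gave 32245. The feature lists were identical, so this is the number of distinct symbols. The excess of shared barcodes depends on the size of the kit list, which was taken from general knowledge: with a list 0.5 times that size, an alternative added after seeing the data, it was 31.1 times, and with the list size of the earlier kit, also added, it was 6.76 times, with highest simulated counts of 93 and 348. A pool of 109137 equally frequent barcodes would give the observed overlap by chance. Other cell filters, clustering resolutions, thinning and another choice of genes for scaling, all listed before the data were examined, were not run, since they act on transcript counts, which were not used here. No paired analysis was possible because each genotype has 1 library, and no library could be left out. No other setting was run on the base content of the barcodes or the exon overlaps of the named genes. The depth of the libraries in transcripts is unknown, so it sets no limit that can be stated.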

Other observations

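The base content of the shared barcodes, examined after the overlap was seen, differed from that of unshared barcodes at many positions. G was less frequent among shared barcodes than in both unshared sets at 16 of 16 positions. C was more frequent at 14 of 16 positions, with 4.27 per shared barcode against 4.005 in WT-only and 4.04 in KO-only barcodes (permutation test against random subsets of either list, adjusted p = 0.0002). A and T did not pass the test, with adjusted p-values of 0.19 and 0.55 against the WT list and 0.85 for both against the KO list. The base counts of a barcode add up to its length, so the differences in G and C are not independent. If droplets with a shared barcode include molecules from the other genotype, a contrast of WT with KO spermatocytes may depend on them, which could be examined by repeating it on the 12051 and 12773 barcodes found in one list only.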
